A study of Homo sapiens with 36 samples.

How the data were processed

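TET1 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HEK293T cells, a human embryonic kidney line, after transfection of 1 of 6 small interfering RNAs (siRNAs). The labels name 36 libraries: 18 from the TET1 pull-down and 18 from input chromatin, with 3 replicates of each kind per siRNA. Per the labels' protocols, sonicated nuclei were immunoprecipitated with an antibody to TET1, fragments of 200 to 500 bp were selected and libraries were amplified over 18 PCR cycles. The submitters' processing notes name FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0, deepTools 3.5.0 and the human build hg19, with no roles or order. Settings of the aligner and the peak caller, duplicate removal and region filters were not given in the sources used here.

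The files analysed here were 6 peak lists, 1 per siRNA, whose names carry replicates 1 to 3 together. The lists were therefore taken as peaks called on pooled replicates, with 1 list per group. The deposited fold enrichment of a peak is the ratio of pull-down to local control at the summit, as the authors' peak caller gave it. The deposited −log10 p-value and −log10 q-value also refer to the summit. The deposited score is 10 times the −log10 q-value, truncated to a whole number. Fold enrichment belongs to the authors' list in which it stands. A deposited peak with several summits appears once per summit, so the lists hold fewer distinct intervals than peaks. Coordinates are given on hg19, counted from 1.

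Peaks of different lists were called overlapping when they shared at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Each overlap with siNC was compared with 1000 random placements of the knockdown list on the same chromosomes, a one-sided permutation test of positions. The smallest p that these placements can give is 0.001. siNC peaks overlapped by a knockdown list were compared in siNC fold with the remaining siNC peaks by a two-sided permutation test of the difference of medians. It used 100000 resamples, and the smallest p it can give is 1e-05. Whether 2 knockdown lists overlapped the same siNC peaks was tested with Fisher's exact test (two-sided) over siNC peaks. P-values were adjusted by the Benjamini-Hochberg method over the 10 overlap shares, the 5 fold comparisons and the 10 pairs of knockdown lists. Peaks are not replicates, so all of these tests compare lists and not cultures. Peak numbers and covered lengths have 1 value per group and were not tested.

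After the data were seen, peaks were placed in 4 classes: the mitochondrial genome, unplaced or alternative sequences, the peak-poor stretch of each chromosome, and the chromosome arms. The peak-poor stretch is the longest interval between consecutive siNC peaks of fold 4 or more, extended by 1 Mb on either side. On most chromosomes it spans the region of the centromere. On chromosome 3 it fell elsewhere, at 0.675 to 4.39 Mb. On chromosome 21 it ended at 9.58 Mb, so peaks such as the one at 11186500 to 11186817 counted as arm peaks. On chromosome Y it ran from 13.5 to 59.2 Mb. The dense clusters on chromosomes 11 and 8, the quartiles of fold and the distal part of chromosome 3 were also chosen after the data were seen.

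Read depth per library was not analysed here, and the lists give no read totals. A relative depth was computed instead. Fold and −log10 p-value together give the pull-down pileup and the control background at each summit, with a pseudocount of 1 in the fold and a tolerance of 0.02 on −log10 p. Between 98.6% of the siCHD3 list and 99.997% of the siNC list could be recovered in this way. The lowest control background was 2.50 reads in siNC, 2.29 in siCHD3, 2.72 in siCHD4, 2.80 in siCHD5, 1.83 in siMBD2 and 2.21 in siMBD3. This value depends on both read number and fragment length.

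Regions named in the text followed a rule written before the data were examined. The rule took the 10 peaks of highest fold in each list, the 10 highest in siNC and absent from siCHD5 and the reverse, and the 10 siNC peaks found in the most knockdown lists. The rule asked for the nearest genes where an annotation of the same build was at hand. The gene table used here is of another assembly, so regions are named by position, and gene names, promoter shares, motifs and base composition were not analysed. Arm peaks of siNC found in the most knockdown lists, and other arm peaks of the small lists, were named after their values were seen.

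The procedures were tested on simulated data. With 28 overlaps planted in a list of 140 peaks like siCHD3, 28 were found. With 71 planted among 358 peaks like siMBD2, 71 were found. With 6549 planted among 32749 peaks like siCHD5, 6713 were found. Among 20 random lists of 32749 peaks like siCHD5, 3 passed a threshold of 0.05, and 1 of 20 did for siCHD3. The permutation test called 1 of 40 sets with no difference and 40 of 40 sets raised by 1.5 times. These runs used fewer placements and resamples than the tests of the deposited lists. Random lists were placed in the same way as in the test, so lists concentrated in a few regions were not tried. Control background was recovered within 1% in 100% of 1657 simulated peaks. Alternatives covered stricter peak thresholds, other overlap definitions, main chromosomes, merged peaks, siNC lists of equal length and ranking by −log10 q. The siNC lists of equal length kept the siNC peaks of highest −log10 q. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.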

Results

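Binding of TET1, a dioxygenase that oxidises 5-methylcytosine, was mapped by ChIP-seq in HEK293T cells, a human embryonic kidney line carrying the SV40 large T antigen. The siRNAs were named for CHD3, CHD4 and CHD5, chromatin-remodelling ATPases of the NuRD complex, and for MBD2 and MBD3, its methyl-CpG-binding domain subunits. The list called siNC was taken as the control because the other siRNAs are named for genes. Each group comprised 3 pull-down and 3 input libraries and has 1 peak list, which was taken as called on the pooled replicates. No spread between replicates could therefore be computed, and every comparison is between 2 lists. Read totals were not analysed here, and the levels of the targeted proteins were not analysed here. Fold enrichment of a peak is the authors' value for its own list.

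This comparison asks where TET1 bound in cells given siRNAs named for single NuRD subunits. TET1 peaks numbered 28450 in siNC, and they covered 8.86 Mb of the genome. siCHD5 held 32749 peaks over 10.2 Mb, 1.15 times the siNC number. The other lists were far shorter: 358 peaks over 119 kb in siMBD2, 259 over 80.3 kb in siMBD3, 140 over 35.2 kb in siCHD3 and 110 over 28.9 kb in siCHD4. These numbers equal 1.26%, 0.910%, 0.492% and 0.387% of the siNC number. Median peak width was 300 bp in siNC, 301 bp in siCHD5 and between 342 bp and 375.5 bp in the shorter lists. Within its own list the median fold was 6.72 in siNC (quartiles 4.96 and 8.99), 6.90 in siCHD5, 4.60 in siMBD2, 4.13 in siMBD3, 1.53 in siCHD3 and 1.44 in siCHD4. With 1 pooled list per group, none of these differences could be set against replicate error.

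**Figure D1:**
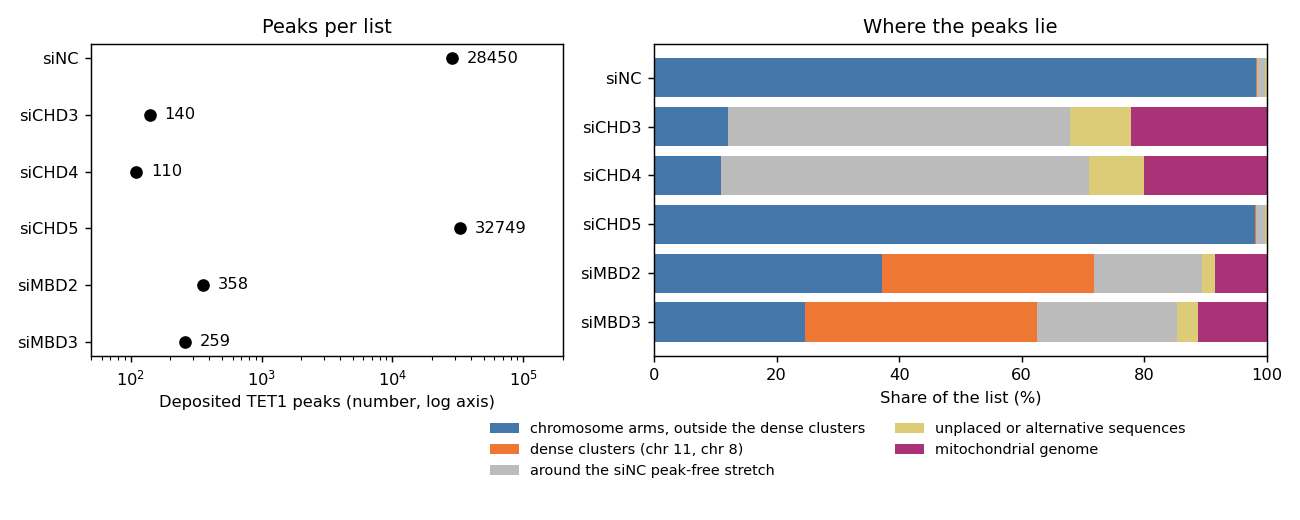
Left, number of deposited TET1 peaks per list on a log axis, from 110 in siCHD4 to 32749 in siCHD5. Right, share of each list (%) by region class. Arms outside the dense clusters hold 98.2% of the siNC list and 10.9% of the siCHD4 list.

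The location of the peaks differed as well. Chromosome arms held 27978 siNC peaks (98.3%, 95% interval 98.2 to 98.5) and 32156 siCHD5 peaks (98.2%). They held 17 siCHD3 peaks (12.1%, 7.24 to 18.7), 12 siCHD4 peaks (10.9%, 5.77 to 18.3), 257 siMBD2 peaks (71.8%, 66.8 to 76.4) and 162 siMBD3 peaks (62.5%, 56.3 to 68.5). The mitochondrial genome carried no peak in siNC or siCHD5. It carried 31 peaks in siCHD3 (22.1%, 15.6 to 29.9), 22 in siCHD4 (20.0%, 13.0 to 28.7), 30 in siMBD2 (8.38%, 5.73 to 11.7) and 29 in siMBD3 (11.2%, 7.63 to 15.7). Mitochondrial peaks had median folds of 1.17 to 1.21 in their own lists. The peak-poor stretches, on most chromosomes around the centromere, held 78 siCHD3 peaks, 66 siCHD4 peaks, 63 siMBD2 peaks and 59 siMBD3 peaks, with median folds of 1.49 to 1.60. The same stretches held 369 siNC peaks and 470 siCHD5 peaks, with median folds of 6.26 and 5.92. The shorter lists thus had a larger share of their peaks there, but not a larger number. The control background recovered at the summits had a median of 379 reads in siCHD3 and 431 in siCHD4, against 3.70 in siNC, 2.33 in siMBD2 and 3.74 in siMBD3. These classes were defined after the data were seen, and the shares were not tested against each other.

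siCHD5 was compared with siNC to see which TET1 sites stayed after CHD5 siRNA. siCHD5 peaks overlapped 24294 siNC peaks (85.4%, 85.0 to 85.8), and each of the 10 siNC peaks of highest fold was among them. The highest lay on chromosome 17 at 43212531 to 43213330, with 44.3-fold enrichment in siNC and a 29.1-fold peak in siCHD5. Further siNC peaks followed on chromosome 17 at 41837676 to 41838177 (32.5-fold), chromosome 7 at 150869517 to 150869997 (29.2-fold), chromosome 16 at 90182560 to 90183025 (29.1-fold), chromosome 16 at 60818 to 61233 (29.0-fold) and chromosome 17 at 17259320 to 17259822 (28.7-fold). The highest siCHD5 peaks lay on chromosome 9 at 130879826 to 130880278 (47.6-fold), chromosome 7 at 150869515 to 150870073 (40.1-fold), chromosome 5 at 111496251 to 111497225 (38.4-fold) and chromosome 12 at 94035 to 94511 (37.6-fold), and siNC also had a peak at each.

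Sites present in only 1 of these lists had lower folds. siNC peaks without a siCHD5 peak numbered 4156, with a median fold of 4.13, against 7.20 for those overlapped (difference 3.07, permutation test, p = 1e-05, the smallest it can give; adjusted p = 1e-05). siCHD5 peaks without a siNC peak numbered 8357, with a median fold of 4.47, against 7.92 for the 24392 that overlapped siNC (permutation test, p = 1e-05). Overlap rose with siNC fold. siCHD5 overlapped 59.6% of siNC peaks in the lowest quartile, 86.9% in the second, 95.6% in the third and 99.4% (99.2 to 99.6) in the highest, where 42 peaks were left without a partner. The strongest siNC peaks absent from siCHD5 lay on chromosome 2 at 50763502 to 50763823 (14.0-fold), chromosome 1 at 162361987 to 162362270 (13.4-fold), chromosome 13 at 99100622 to 99100942 (13.2-fold) and chromosome X at 37604633 to 37604999 (13.0-fold). The strongest siCHD5 peaks absent from siNC lay on chromosome 5 at 179061290 to 179061965 (15.8-fold), chromosome 6 at 162169865 to 162170188 (15.5-fold), chromosome 14 at 65630845 to 65631206 (14.8-fold) and chromosome 17 at 36762520 to 36762952 (14.5-fold). Random placement of the siCHD5 list overlapped 213 siNC peaks on average (one-sided permutation p = 0.001, the smallest that 1000 placements can give; adjusted p = 0.001).

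siCHD3 and siCHD4 peaks covered almost none of the siNC sites. siCHD3 peaks overlapped 51 siNC peaks (0.179%, 0.134 to 0.236) and siCHD4 peaks overlapped 48 (0.169%, 0.124 to 0.224). On the chromosome arms these numbers were 6 and 5. The siCHD3 peaks of highest fold lay on chromosome 6 at 862642 to 862921 (5.17-fold, in no other list), chromosome 1 at 21695051 to 21695232 (5.12-fold, also in siNC and siCHD5), chromosome 7 at 61185907 to 61186109 (4.87-fold, in a peak-poor stretch and in no other list) and chromosome 15 at 89200673 to 89200856 (4.87-fold, also in siNC and siCHD5). In siCHD4 they lay on chromosome 13 at 25861912 to 25862117 (5.92-fold, in no other list), chromosome 14 at 50053655 to 50053843 (5.44-fold, also in siNC and siCHD5) and chromosome 12 at 58299202 to 58299389 (5.05-fold, also in siNC and siCHD5). The strongest siNC site, on chromosome 17 at 43212531, kept a siCHD4 peak of 4.84-fold. Small as they were, the overlaps exceeded random placement, which gave 0.878 and 0.896 siNC peaks on average (one-sided permutation p = 0.001 and adjusted p = 0.001 for both). Placement was uniform along each chromosome, while 44 of 53 siCHD3 and 43 of 51 siCHD4 peaks over siNC lay in the peak-poor stretches. The test therefore does not separate shared TET1 sites from shared regions of high signal. Seen from the shorter lists, 53 of 140 siCHD3 peaks (37.9%, 29.8 to 46.4) and 51 of 110 siCHD4 peaks (46.4%, 36.8 to 56.1) overlapped siNC. With siNC limited to as many peaks as the list, taken from the highest −log10 q, these shares were 2.86% and 3.64%. The siNC peaks overlapped had a median −log10 q of 10.3 and 9.82, against 16.55 for the remaining siNC peaks. Length and rank of the siNC list thus changed together.

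siMBD2 and siMBD3 peaks also covered few siNC sites, but more of their peaks lay on the arms. siMBD2 peaks overlapped 71 siNC peaks (0.250%, 0.195 to 0.315) and siMBD3 peaks overlapped 50 (0.176%, 0.130 to 0.232). On the arms these numbers were 29 and 11. Strong siNC sites with a siMBD2 peak included chromosome 17 at 43212531 to 43213330 (5.09-fold in siMBD2), chromosome 16 at 60818 to 61233, chromosome 14 at 50328694 to 50329228 (24.7-fold in siNC) and chromosome 14 at 67826524 to 67827124 (22.99-fold in siNC). The siMBD2 peaks of highest fold lay on chromosome Y at 58827145 to 58827539 (21.6-fold, in a peak-poor stretch), chromosome 11 at 35588625 to 35590900 (18.3-fold) and chromosome 21 at 11186500 to 11186817 (15.5-fold), and siMBD3 had a peak at each. The window on chromosome Y at 58 to 59 Mb held 8 siMBD2 and 4 siMBD3 peaks, and 0 peaks of siNC, siCHD3, siCHD4 and siCHD5. Whether the reads placed there came from chromosome Y was not tested, so these peaks were not read as TET1 binding on that chromosome. Random placement overlapped 2.93 siNC peaks for siMBD2 and 2.13 for siMBD3 on average (one-sided permutation p = 0.001 and adjusted p = 0.001 for both). Placement was uniform here too, so the test has the same limit as for siCHD3 and siCHD4. Of the list peaks, 74 in siMBD2 (20.7%, 16.6 to 25.2) and 57 in siMBD3 (22.01%, 17.1 to 27.6) overlapped siNC. These shares were 12.1% and 8.02% on the arms, and 3.07% and 2.70% with siNC limited to as many peaks as the list.

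A large part of both MBD lists fell in a pair of dense clusters. On chromosome 11 between 34 and 36 Mb, siMBD2 had 95 peaks and siMBD3 had 75, while siNC and siCHD5 had 27 each. On chromosome 8 between 32 and 33 Mb the numbers were 29 in siMBD2, 23 in siMBD3, 4 in siNC and 7 in siCHD5. siCHD3 and siCHD4 had 0 peaks in either cluster. The strongest cluster peak lay on chromosome 11 at 35588625 to 35590900 (18.3-fold in siMBD2), where siMBD3 had a 12.2-fold peak and siNC and siCHD5 had peaks as well. Other prominent cluster peaks lay on chromosome 11 at 35132397 to 35134477 (13.8-fold in siMBD2), at 35164595 to 35166198 (10.6-fold in siMBD2) and at 35030254 to 35031339 (10.6-fold in siMBD3). Cluster peaks made up 34.6% of the siMBD2 list (29.7 to 39.8) and 37.8% of the siMBD3 list (31.9 to 44.0). Counted as distinct intervals, 1 of 88 siMBD2 intervals in the clusters overlapped siNC (1.14%, 0.0288 to 6.17), against 26 of 126 on the remaining arms (20.6%, 13.9 to 28.8). In siMBD3 the numbers were 1 of 63 (1.59%, 0.0402 to 8.53) and 8 of 59 (13.6%, 6.04 to 24.98). The cluster bounds were chosen after the data were seen, for their many siMBD2 and siMBD3 peaks, so these shares were not read as a test.

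**Figure D2:**
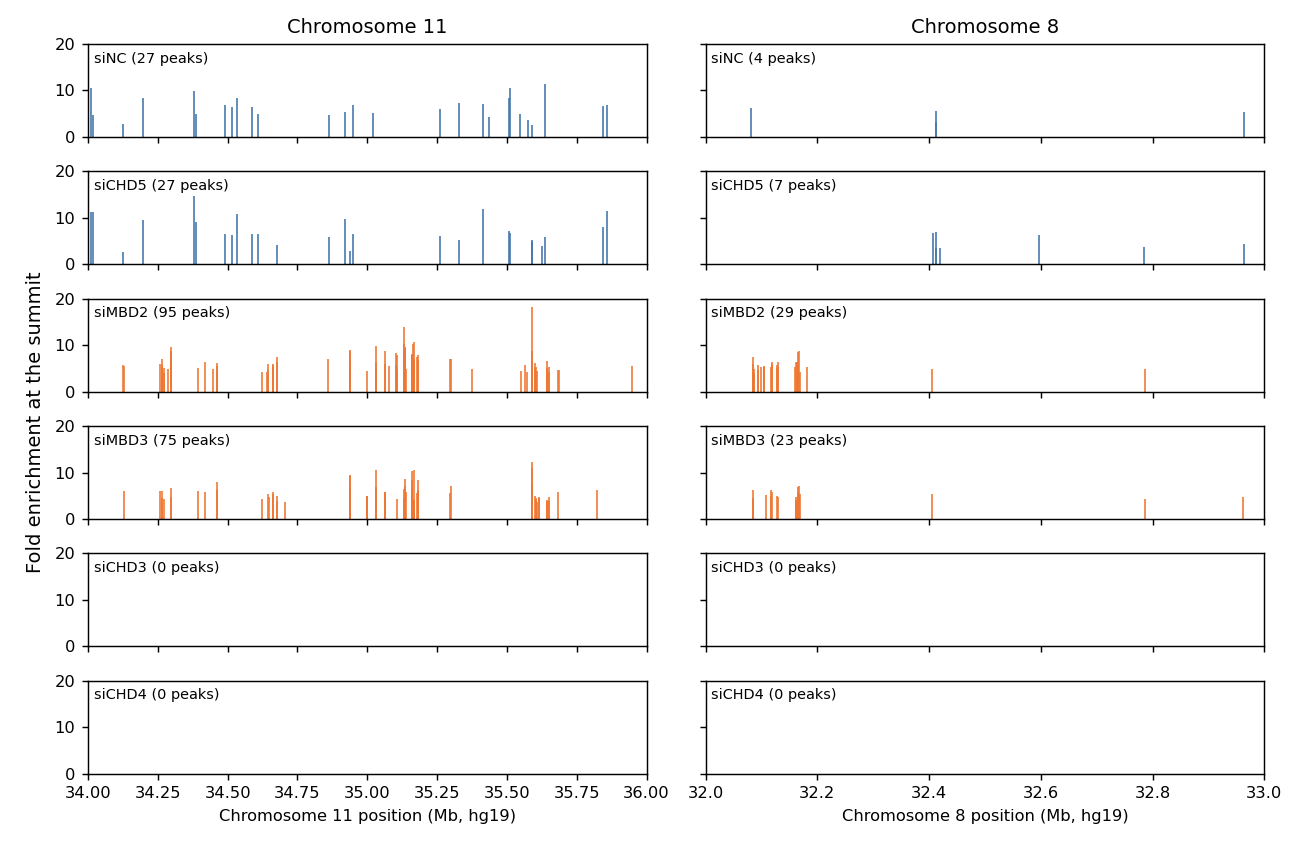
TET1 peak summits on chromosome 11 (34 to 36 Mb) and chromosome 8 (32 to 33 Mb), hg19. Each line is 1 peak and its height is the fold enrichment in its own list; siMBD2 has 95 and 29 peaks in these regions, and siCHD3 and siCHD4 have 0.

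The siNC sites that kept a peak in the shorter lists were mainly sites of low siNC fold. Their median siNC fold was 1.41 for siCHD3, 1.39 for siCHD4, 1.61 for siMBD2 and 1.44 for siMBD3, against 6.74 for the remaining siNC peaks. The differences were −5.32, −5.34, −5.12 and −5.29 (permutation test, p = 1e-05, the smallest it can give; adjusted p = 1e-05 for each). On the arms alone the picture changed. The median was 10.3 against 6.74 for siMBD2 (29 peaks, permutation p = 1e-05, adjusted p = 2.5e-05) and 10.8 against 6.75 for siCHD4 (5 peaks, permutation p = 0.02, adjusted p = 0.0333). For siCHD3 it was 6.40 against 6.75 (6 peaks, permutation p = 0.801, adjusted p = 0.801), and for siMBD3 4.78 against 6.75 (11 peaks, permutation p = 0.072, adjusted p = 0.09). The split by arms was chosen after the data were seen, and a fold minimum of 4 in every list also turned the direction for all 4 shorter lists. Ranked by −log10 q in place of fold, the siMBD2 difference no longer passed the test (−1.07, permutation p = 0.589).

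**Figure D3:**
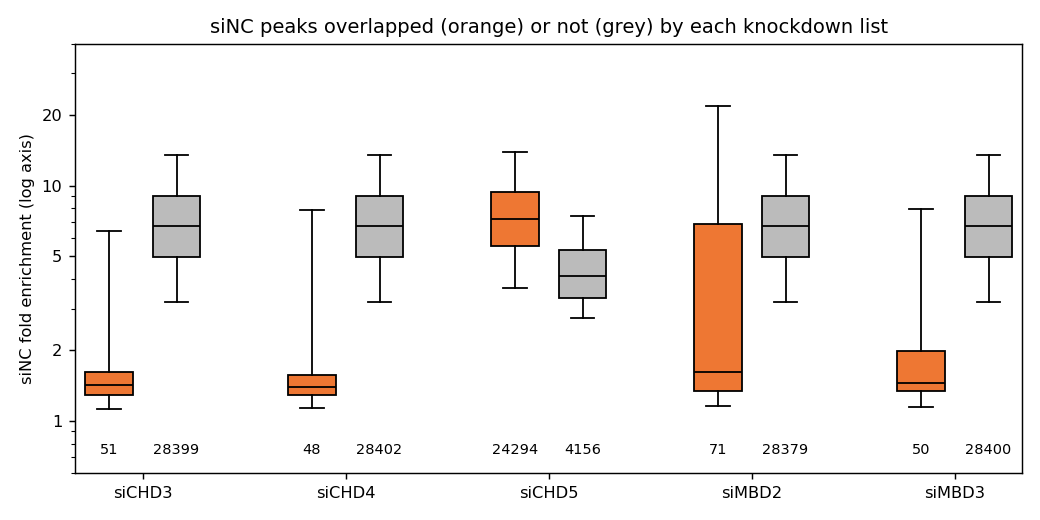
siNC fold enrichment (log axis) of siNC peaks overlapped by each knockdown list, in orange, and of the remaining siNC peaks, in grey, with the number of peaks under each box. Boxes give the median and quartiles and whiskers the 5th and 95th percentiles; medians of overlapped peaks are 1.39 to 1.61 in the shorter lists and 7.20 in siCHD5.

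The shorter lists shared their siNC sites with each other. siCHD3 and siCHD4 overlapped the same 39 siNC peaks, where 0.0860 would be expected of independent lists (Fisher's exact test, adjusted p = 1.08e-106 over 10 pairs). The other pairs among siCHD3, siCHD4, siMBD2 and siMBD3 shared 37 to 40 siNC peaks, with adjusted p of 1.73e-91 or lower. siCHD5 overlapped most of these sites as well: 46 of 51 for siCHD3, 45 of 48 for siCHD4, 66 of 71 for siMBD2 and 46 of 50 for siMBD3. Because siCHD5 overlapped 85.4% of all siNC peaks, 43.5, 41.0, 60.6 and 42.7 were expected. The test therefore had little room to pass, and no pair with siCHD5 did (Fisher's exact test, adjusted p from 0.128 to 0.428). On chromosomes 1 to 22, X and Y alone, siCHD4 and siCHD5 passed (43 shared, Fisher's exact test, adjusted p = 0.0235). In all 5 knockdown lists 31 siNC peaks were overlapped, of which 29 lay in the peak-poor stretches and 0 on the arms. They included chromosome 11 at 51580174 to 51580652 (2.02-fold in siNC), chromosome 18 at 18519082 to 18519502 (1.85-fold), chromosome 19 at 27731953 to 27732324 (1.81-fold) and chromosome 10 at 42400237 to 42400660 (1.62-fold). The arm peak found in most lists, on chromosome 7 at 24101 to 24378 (2.15-fold in siNC), was present in siCHD3, siCHD4, siCHD5 and siMBD2. Of the siNC arm peaks, 23873 were overlapped by siCHD5 and by none of the other knockdown lists. Several of these peaks share an interval, so they are not independent, and the pairs among the 4 shorter lists shared 0 to 4 siNC peaks on the arms and 0 to 2 at a fold minimum of 4.

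The shorter lists were also laid directly over each other. Of 259 siMBD3 peaks 190 overlapped siMBD2 (73.4%), and of 110 siCHD4 peaks 86 overlapped siCHD3 (78.2%) and 77 overlapped siMBD2 (70.0%). In the other direction, 183 of 358 siMBD2 peaks overlapped siMBD3 (51.1%), 90 of 140 siCHD3 peaks overlapped siCHD4 (64.3%) and 80 of 358 siMBD2 peaks overlapped siCHD4 (22.3%). On the arms, 107 of 162 siMBD3 peaks overlapped siMBD2, but only 21 of 64 outside the clusters. For siMBD2 peaks over siMBD3 these numbers were 105 of 257 and 22 of 133. Among the CHD lists, 7 of 12 siCHD4 arm peaks overlapped siCHD3, among them low-fold summits on chromosome 1 at 566156 to 566677 (1.49-fold and 1.61-fold). On the arms 3 of 17 siCHD3 peaks overlapped siMBD3 and 4 of 17 overlapped siMBD2, and 4 of 12 siCHD4 peaks overlapped each of siMBD2 and siMBD3. In the other direction, siCHD3 and siCHD4 were overlapped by 2 and 3 of 162 siMBD3 arm peaks and by 4 and 4 of 257 siMBD2 arm peaks. These direct overlaps were not tested.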

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

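The tests of the peak threshold and of copy gain were chosen after the results were seen. siCHD5 stood apart because its list was longer than siNC (32749 against 28450 peaks) while the other 4 knockdown lists were shorter, and this difference was not tested.

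siCHD3, siCHD4, siMBD2 and siMBD3 held 110 to 358 peaks against 28450 in siNC, and lower depth of the pooled libraries is argued against: siNC peaks scaled to the siMBD2 depth (0.731 of siNC) and held to that list's lowest −log10 p still numbered 25114. A stricter threshold is argued against as well, since 26359 siNC peaks reached the highest lowest −log10 p of the 4 lists (6.31, in siCHD4). A lower yield of the TET1 pull-down would leave the strongest siNC sites. Over whole lists the retained sites had a lower siNC fold in each of the 4, but this does not speak against lower yield. Most list peaks over siNC lay in the peak-poor stretches: 44 of 53 in siCHD3, 43 of 51 in siCHD4, 39 of 74 in siMBD2 and 38 of 57 in siMBD3. Peaks there had median folds of 1.49 to 1.60 and median pileups of 358 to 534 reads in these lists, so their presence says little on yield. The arms leave out the low-fold siNC sites of those stretches by construction but keep other low-fold sites, down to 1.76-fold. On the arms the retained sites had a higher fold at p below 0.05 in 2 of the 4 lists, in siCHD4 on 5 peaks, so this test decides nothing. Lower yield and a loss of TET1 binding after the siRNA, the biological explanation the design names, cannot be told apart, because each group has 1 pooled list and TET1 levels were not analysed here.

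siMBD2 and siMBD3 shared dense clusters on chromosome 11 (95 and 75 peaks) and chromosome 8 (29 and 23 peaks). Copy gain in the cells would raise pull-down and control alike, so it would not by itself give the median folds on chromosome 11 (5.66 and 5.34). The upper quartile of the control background at cluster peaks was 1.46 times the lowest value in siMBD2 and 1.61 times in siMBD3. No control gain of the size of these folds was therefore seen at called peaks, and the background elsewhere in the clusters is not known. The bound on the quartile was set after an earlier one on the median, 1.09 and 1.34 times, had left the question undecided, so a small gain stays open. DNA of another library or construct in the pull-down and TET1 binding gained after both siRNAs cannot be told apart, since either may give the overlap of 87.8% of siMBD3 cluster peaks with siMBD2 cluster peaks (66.9% in the other direction).

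siCHD5 exceeded siNC in peak number. Deeper siCHD5 libraries are argued against as the whole cause: scaled to the siNC background and held to the siNC list's lowest −log10 p, 31813 siCHD5 peaks were left. A different pull-down yield and an effect of the CHD5 siRNA stay open and were not tested.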

How the results depend on the processing

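The arm and cluster settings were chosen after seeing the data. Each of the 70 alternative overlap shares with siNC stayed above random placement at p below 0.05, but several moved in size. With siNC limited to as many peaks as the list, the share of list peaks over siNC was 2.86% in siCHD3, 3.64% in siCHD4, 3.07% in siMBD2 and 2.70% in siMBD3, and the share of siNC peaks overlapped was 2.14%, 2.73%, 2.51% and 1.54%. At a fold of 4 or more the list share was 8.61% in siMBD2, 3.55% in siMBD3 and 75% (3 of 4 peaks) in siCHD4, and the siNC share was 0.00807% in siCHD3, 0.0121% in siCHD4, 0.0807% in siMBD2 and 0.0242% in siMBD3. At a −log10 q of 5 or more the siNC share was 0.151% in siMBD2 and 0.115% in siMBD3. On the arms the list share was 12.1% in siMBD2 and 8.02% in siMBD3, and the siNC share 0.0214% in siCHD3, 0.0179% in siCHD4, 0.104% in siMBD2 and 0.0393% in siMBD3. On the arms without the clusters the list share was 14.1% in siMBD3, and the siNC share was 0.0215% in siCHD3, 0.0179% in siCHD4, 0.100% in siMBD2 and 0.0358% in siMBD3. Without gene or genome references of the same build, the alternatives for annotation shares, gene list promoters, CTCF motifs and base composition were not run. No paired analysis was possible because each group has 1 list, taken as called on pooled replicates. Leaving out single replicates was not possible for the same reason. Read totals were not analysed here, and scaling siNC to the siMBD2 depth and threshold left 25114 of 28450 peaks. Peak numbers at a −log10 q of 5 or more were 196 in siMBD2 (76.6 kb covered) and 136 in siMBD3 (50.5 kb). At a fold of 4 or more they were 6 in siCHD3 (1.25 kb), 4 in siCHD4 (0.778 kb) and 141 in siMBD3 (51.1 kb). Main chromosomes alone left 23.4 kb in siCHD3 and 19.2 kb in siCHD4. On the arms the numbers were 17, 12 and 162 in siCHD3, siCHD4 and siMBD3, the same with the stretch taken from siCHD5, and 19, 13 and 166 with a 0.5 Mb flank. Without the clusters 234 siMBD2 and 161 siMBD3 peaks were left. The siNC fold difference of overlapped peaks turned at a fold of 4 or more, to 7.96 (siCHD3, 2 peaks), 7.58 (siCHD4, 3 peaks), 4.38 (siMBD2) and 0.688 (siMBD3, permutation p = 0.587). On the arms it was −0.343 (siCHD3, permutation p = 0.801), 4.06 (siCHD4), 3.56 (siMBD2) and −1.98 (siMBD3, permutation p = 0.072). Ranked by −log10 q, the siMBD2 difference was −1.07 (permutation p = 0.589). By their construction the arm and fold settings leave out the low-fold peaks around centromeres; other causes were not tested. At a fold of 4 or more, shared siNC peaks fell to 0 for siCHD3 with siCHD4, siMBD2 and siMBD3 and for siCHD4 with siMBD3, to 1 for siCHD4 with siMBD2, to 2 for siMBD2 with siMBD3 and to 5 for siCHD5 with siMBD3. On the arms they were 0 for siCHD3 with siMBD3, 1 for siCHD3 with siCHD4 and siCHD4 with siMBD3, 2 for siMBD2 with siCHD3 and siCHD4, 4 for siMBD2 with siMBD3, 5 for siCHD3 with siCHD5 and 9 for siCHD5 with siMBD3. siCHD5 shared 2, 3 and 20 with siCHD3, siCHD4 and siMBD2 at a fold of 4 or more, and 5 with siCHD4 and 27 with siMBD2 on the arms. Among the 4 shorter lists 1 shared peak there sufficed to pass Fisher's exact test, so passing says little. On main chromosomes siCHD4 and siCHD5 shared 43 (Fisher's exact test, adjusted p = 0.0235).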

Other observations

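The regions described here were chosen after seeing the data. TET1 peaks were unevenly spread over the chromosomes in both siNC and siCHD5. In siNC the density was highest on chromosome 17 (18.6 peaks per Mb) and chromosome 19 (17.9), followed by chromosome 22 (12.0), and among autosomes it was lowest on chromosome 21 (5.63), chromosome 18 (6.06) and chromosome 13 (6.35). In siCHD5 the values were 21.5 on chromosome 17, 21.2 on chromosome 19 and 6.32 on chromosome 21. Densities were taken over the length up to the last peak end in any list. That length counts starts without siNC peaks of fold 4 or more, up to 19.9 Mb on chromosome 13 and 9.58 Mb on chromosome 21. The order of the sparsest autosomes may depend on it. The densest 1 Mb window in siNC lay on chromosome 17 at 46 to 47 Mb, with 52 siNC and 55 siCHD5 peaks, followed by chromosome 1 at 156 to 157 Mb (48 and 50), chromosome 19 at 48 to 49 Mb (47 and 49) and chromosome 16 at 30 to 31 Mb (46 and 55). In each of these 4 windows siCHD3, siCHD4, siMBD2 and siMBD3 had 0 peaks.

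The distal long arm of chromosome 3, at 160 to 200 Mb, held 23 of the 26 siMBD2 peaks and 11 of the 11 siMBD3 peaks on that chromosome. siNC had 240 of its 1531 chromosome 3 peaks there, and siCHD5 had 300 of 1790. The window on chromosome 2 at 92 to 93 Mb had peaks in every list: 20 in siNC, 22 in siCHD5, 16 in siCHD3, 15 in siCHD4, 11 in siMBD2 and 14 in siMBD3. A peak on chromosome 1 at 566148 to 566685 (1.48-fold in siCHD3) was shared by siCHD3, siCHD4, siMBD2 and siMBD3 and absent from siNC and siCHD5. These are the same lists that carried mitochondrial peaks, and its folds were low in each, from 1.42 in siMBD3 to 1.63 in siMBD2. The peak counts among the arm peaks of each of these lists. Whether it reflects TET1 binding at this nuclear position was not tested.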
